A study of Mus musculus with 10 samples.

How the data were processed

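Liver RNA of 10 male C57BL/6N mice was hybridised to 2-colour Agilent mouse arrays of 45018 spots. Per the labels, total RNA from fresh liver was extracted with Trizol, purified on Qiagen columns, converted to cDNA with an indirect labelling kit, and coupled to Cy5, and a commercial mixed mouse RNA in Cy3 served as the reference on every array. The labels also give liver as the tissue of the reference channel. The groups were maltose control (3 arrays), 5 g/kg ethanol (4 arrays) and 7 g/kg ethanol (3 arrays).

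Per the file headers, Agilent Feature Extraction 11.5.1.1 measured the median pixel intensity of each spot and of its local background in both channels, without normalization. The deposited processed intensity of each channel was background subtracted, spatially detrended and dye normalized by the same software, per the file headers. The deposited log10 ratio of red over green processed signal came from this software, per the file headers. The deposited series table holds log2 ratios of liver over reference for 40599 probes. This log2 scale was read from its values, which had a slope of 3.32 to 3.34 on the log10 ratio and r of 0.94 to 1.00 with it. Its column medians were 0.062, 0.025 and 0.014 in controls, −0.042, −0.010, −0.066 and 0.045 at 5 g/kg, and 0.014, −0.073 and 0.076 at 7 g/kg, and no header or label states a step between the scanner ratio and this table.

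The main values were computed from the median intensities in R 4.3.3 with limma 3.58.1: normexp background correction with an offset of 50, loess normalization of the log2 ratio within each array, and averaging of the spots of a probe. Control spots were left out, and so were spots that the scanner software marked as outliers (2.42% to 5.83% per array). No spot was saturated. Of 41174 probes, 24375 (59.2%) matched a gene symbol through their RefSeq accession and the reference annotation of GRCm38.p6. The array design was built on mm8, so no coordinates are given. Probes whose liver channel stood well above background on fewer than 3 arrays were left out, and 33943 remained. Genes with fewer than 2 values in any group were also left out, a rule added after seeing the data. Where a gene had several probes, that with the highest mean signal was used, which left 26124 genes, 15112 of them with a symbol. Of their values 1.42% were missing, in 9.12% of genes.

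All 10 arrays entered 1 limma fit of 3 group means with empirical Bayes moderation (7 residual and 7.24 prior degrees of freedom), and the comparisons were 5 g/kg minus control, 7 g/kg minus control and 7 minus 5 g/kg. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. The median SE of a log2 change was 0.12, 0.128 and 0.12. Before the data were examined, 36 gene lists of liver pathways and cell types were fixed, with 619 genes, 587 on the array and 524 tested. Some genes stand in several lists, so lists that share members are not independent. Mt1 and Mt2 are in the NRF2 and glucocorticoid target lists, and Cdkn1a is in the p53 and glucocorticoid target lists. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with missing values filled by the group mean. Alternatives were camera with an estimated correlation and limma's fry, which asks whether the genes of a list move 1 way on balance and compares the list with no other genes. With camera 18, 16 and 11 lists passed in the 3 comparisons. With an estimated correlation 1, 2 and 0 lists passed. With fry 18, 20 and 4 passed.

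Named genes were chosen by a rule fixed in advance. It takes the 10 highest and 10 lowest log2 changes among passing genes whose groups do not overlap, leaving out names that are only clone or probe identifiers. It adds up to 4 members of each list with the smallest p, and 30 genes named whatever their result. Of these 30, Atf4, Hspa5 and Scd1 were on the array but not tested, because the scanner software marked their spots as outliers. A few genes chosen by the rule are not reported here, and those few were left out of the search for distant arrays after it had been run. The search covered the other genes chosen by the rule, including those whose changes the text does not give.

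The files show 4 slides, each scanned once, and no slide holds 1 group alone. A fit with slide as a block was therefore run, and differences were computed within each slide that holds both groups. Other alternatives changed the background correction, the normalization, the channel (Cy5 alone, quantile normalized), the source of the values (scanner processed signals or the series table), the filter, the choice of probe, the empirical Bayes settings, array weights, the replicate number as a block and the threshold, and left out each array in turn. Keeping the outlier-marked spots and running the lists and the agreement of doses with slide as a block were added after seeing the data.

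The steps were tested on simulated data of the same size, in which 67, 67 and 66 of 26124 genes were changed by a log2 of 0.5, 1 and 2. At 5 g/kg against control, 29.9%, 91.0% and 100% of these changes were recovered. At 7 g/kg against control the shares were 28.4%, 79.1% and 100%, and between doses 41.8%, 91.0% and 100%. There were 10, 7 and 6 false calls. A list shifted by 0.5 was found in each comparison, with 0 other lists called. The simulated genes varied independently, so this cannot show how often camera calls unchanged lists of correlated genes. The estimated correlation was 0.554 for the ER chaperone list and 0.728 for the acute phase list. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.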

Results

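Liver RNA of male C57BL/6N mice was measured on 10 two-colour arrays. By the labels, 3 mice received maltose by gavage at the calories of 5 g/kg ethanol, 4 mice received 5 g/kg ethanol and 3 mice received 7 g/kg ethanol. Each array held the RNA of 1 replicate against a common mouse reference RNA, so the p-values measure the spread between arrays. The labels give no time between gavage and collection. The median liver signal was 121 to 219 units per array over a local background of 21 to 24 units, and 67.3% to 86.3% of the spots stood well above background. The number of arrays limits the precision. On the first principal component, which held 38.4% of the variance, the control arrays lay at −32.8 to −24.9, the 7 g/kg arrays at 19.6 to 29.9 and the 5 g/kg arrays in between, from −2.17 upwards. On the second, which held 12.9%, the 5 g/kg arrays lay at −20.15 to −3.15, apart from all control and 7 g/kg arrays at 2.34 to 14.43. Log2 changes are given with n = 4 arrays at 5 g/kg, 3 at 7 g/kg and 3 controls, and a smaller n is stated.

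The comparison of 5 g/kg ethanol with maltose asked which liver transcripts differed between ethanol and maltose at matched calories, in a series whose title names ER stress, adipocyte death and lipolysis. No group received neither ethanol nor maltose. Each rise or fall against control is therefore a difference between ethanol and maltose and cannot be assigned to either. The largest rises were in Cyp2b13, at 27.0-fold (log2 4.75, SE 0.247, adjusted p = 3.95e-07, n = 3 and 3), and in Cyp2b10, at 23.2-fold (log2 4.54, SE 0.284, adjusted p = 4.76e-06, n = 2 and 3). These genes encode drug-metabolising P450 enzymes of near-identical sequence, so each probe may read more than 1 of them, and a second Cyp2b13 probe gave a log2 change of 0.165. Lcn2, an iron-carrier-binding protein of the acute phase, rose 9.24-fold (log2 3.21, SE 0.464, adjusted p = 0.0014). The metal-binding metallothioneins Mt1 and Mt2 rose 7.78-fold and 5.35-fold. Creld2, an ER protein induced by misfolded protein, rose 5.78-fold (log2 2.53, SE 0.229, n = 3 and 3), as much as the cell cycle inhibitor gene Cdkn1a (log2 2.53, SE 0.143).

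Among the other large rises at 5 g/kg were Cyp2c70 (log2 2.64, n = 3 and 3), which makes muricholic acids, and Insig2 (log2 2.45), whose product holds sterol regulatory proteins in the ER. Acot3, a peroxisomal acyl-CoA thioesterase gene, changed by −2.97 (SE 0.182, adjusted p = 8.78e-07), and 2 of its 4 ethanol arrays did not stand well above background. The clock output gene Dbp was 3.84-fold lower (log2 −1.94, SE 0.126) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 3.05-fold lower (log2 −1.61, SE 0.362, adjusted p = 0.0229). Adh4, an alcohol dehydrogenase gene, was 2.86-fold lower. Hsd3b5, a male-predominant steroid reductase gene, changed by −1.90, Serpina6, which encodes corticosteroid-binding globulin, by −1.60, and the sterol exporter gene Abcg8 by −1.40. Apol7a (−1.65), Inmt (−1.53) and Tk1 (−1.46) completed the 10 largest falls.

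In all, 992 of 26124 genes passed at 5 g/kg, 582 higher and 410 lower, and 204 of them differed at least 2-fold. With slide as a block, 909 genes passed. Within slides, Lcn2 rose by 1.41 to 4.05, Mt1 by 1.91 to 3.32 and Creld2 by 2.16 to 2.96, while Acot3 changed by −3.40 to −2.48. The count rested on few controls: it was 467 without control 1, 636 without control 2 and 503 without control 3. Of the calls, 58.7% were higher, and 75.4% were with median centring in place of the loess curve.

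Genes of ER chaperones and ER-associated degradation formed the second most strongly shifted list at 5 g/kg. Of its 17 measured members 10 rose, 14 when adjusted over the list alone, and none fell (median log2 0.845, adjusted p = 2.05e-16). Besides Creld2, the ER chaperone gene Hsp90b1 rose by 1.38, Sdf2l1 by 1.55 and Dnajc3 by 0.84 (n = 3 and 3). The list had adjusted p = 0.142 with an estimated correlation, a slide-block median of 0.845 and within-slide medians of 0.358 to 1.15. Genes under the stress-response factors ATF4 and CHOP shifted less, with 2 of 20 higher, 8 when adjusted over the list alone (median 0.184, adjusted p = 0.00206, adjusted p = 0.151 with an estimated correlation). Ddit4 rose by 1.16 and Ero1a by 0.41, while Ddit3, which encodes CHOP, stood at 0.44 (adjusted p = 0.0771), Atf3 at 0.74 (adjusted p = 0.193), Fgf21 at 1.00 (adjusted p = 0.0533) and Trib3 at −0.05 (adjusted p = 0.878). Xbp1, a transcription factor gene of the ER response, stood at 0.51 (adjusted p = 0.129).

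Acute phase protein genes shifted most at 5 g/kg: 12 of 20 rose, 18 when adjusted over the list alone (median log2 1.28, adjusted p = 2.14e-18, adjusted p = 0.143 with an estimated correlation). Haptoglobin (Hp) rose by 1.88, the fibrinogen gene Fga by 1.45 (n = 3 and 3) and the lipopolysaccharide-binding protein gene Lbp by 0.99. The 4 arrays at 5 g/kg spread widely on this list, from 0.344 to 2.11. The within-slide medians were 0.349 to 1.34 and the slide-block median was 1.11. Saa1 stood at 2.35 with an SE of 0.788 and did not pass (adjusted p = 0.135). Glucocorticoid target genes rose in 5 of 13 cases, 10 when adjusted over the list alone (median 0.59, slide-block median 0.64, within slides 0.47 to 0.905, adjusted p = 2.59e-10), with Sgk1 at 0.96 besides Mt1, Mt2 and Cdkn1a. This was the single list at 5 g/kg that also passed with an estimated correlation (adjusted p = 0.0377). Immediate early genes rose in 5 of 15 cases and fell in 1, 7 and 1 when adjusted over the list alone (median 0.382, slide-block median 0.362, adjusted p = 1.17e-05, adjusted p = 0.151 with an estimated correlation). Klf4 rose by 0.94 and Jund by 0.89, and Jun was at least 1.60-fold higher, since its control signal did not stand well above background.

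Genes of ethanol, acetaldehyde and acetate metabolism were lower at 5 g/kg: 4 of 11 fell, 8 when adjusted over the list alone, and none rose (median −0.338, slide-block median −0.339, within slides −0.401 to −0.255, adjusted p = 3.94e-07, adjusted p = 0.137 with an estimated correlation). Adh1, the main liver alcohol dehydrogenase gene, fell by 0.61 and the aldehyde dehydrogenase gene Aldh3a2 by 0.70. Cyp2e1, the ethanol-oxidising P450 gene, stood at −0.34 (adjusted p = 0.23) and Aldh2 at −0.16 (adjusted p = 0.788, n = 2 and 2). Of 17 genes for esterases, lipases and transferases that can use ethanol without oxidation, 1 rose and 2 fell, 1 and 3 when adjusted over the list alone (median −0.092, adjusted p = 0.0225, adjusted p = 0.377 with an estimated correlation). The sulfotransferase gene Sult1a1 rose by 1.36, the carboxylesterase gene Ces1f fell by 0.60 and Ces1d fell by 0.80 (adjusted p = 0.0375, n = 2 and 2). With slide as a block, neither carboxylesterase gene passed, although the changes were −0.63 (adjusted p = 0.0561) and −0.86 (adjusted p = 0.066).

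PPARα target genes of fatty acid oxidation were also lower at 5 g/kg, with 5 of 22 lower and 1 higher, 9 and 2 when adjusted over the list alone (median −0.283, slide-block median −0.25, within slides −0.374 to −0.166, adjusted p = 4.77e-07, adjusted p = 0.142 with an estimated correlation). Ppara itself fell by 1.26, the ketone body gene Bdh1 by 1.25 and Cpt1a, which gates fatty acid entry into mitochondria, by 1.17. Cyp4a14 stood at −0.10 (adjusted p = 0.866). Of 15 lipogenic genes, 2 rose, also 2 when adjusted over the list alone, and the list did not pass (median 0.118, adjusted p = 0.0549), although it did with slide as a block (adjusted p = 0.0126). The risen genes were Fasn, fatty acid synthase, at 3.32-fold (log2 1.73, SE 0.305, n = 3 and 3) and Thrsp, a lipogenic regulator, at log2 1.94 (SE 0.427). Lipid droplet and lipolysis genes showed 2 of 19 higher, 5 and 1 lower when adjusted over the list alone (median 0.146, adjusted p = 0.027, adjusted p = 0.392 with an estimated correlation), and their within-slide medians ran from −0.162 to 0.428. The droplet coat genes Plin3 and Plin5 rose by 0.64 and 0.54 (Plin5 0.60 with slide as a block, adjusted p = 0.0506). The lipase genes Pnpla2 (0.05) and Lipe (0.01) and the droplet genes Plin2 (0.14), Cidea (0.16, n = 2 and 2) and Cidec (1.01, adjusted p = 0.158) did not pass, although Cidec did with slide as a block (1.06, adjusted p = 0.00572).

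Further lists passed at 5 g/kg with a preset correlation and not with an estimated one. The p53 target list had 3 of 17 higher, 5 and 1 lower when adjusted over the list alone (median 0.226, adjusted p = 2.51e-05, adjusted p = 0.137 with an estimated correlation). Cdkn1a, also counted as a glucocorticoid target, stood at 2.53 and Trp53inp1 at 2.30 (n = 3 and 3). Cytosolic and mitochondrial heat shock genes had 4 of 13 higher and 1 lower, 5 and 2 when adjusted over the list alone (median 0.2, adjusted p = 0.00604, adjusted p = 0.189 with an estimated correlation): the chaperone genes Hspb1 and Hsp90aa1 (n = 3 and 3) rose by 1.39 and 1.47, and Hspa8 (n = 2 and 3) fell by 1.31. Xenobiotic P450 genes had 5 of 18 higher and 2 lower, 6 and 4 when adjusted over the list alone (median 0.127, within slides −0.044 to 0.195, adjusted p = 0.0084, adjusted p = 0.151 with an estimated correlation), with Cyp2b9 at 2.36 (n = 2 and 3) and Cyp2c29 at 1.50 (n = 4 and 2). Cell death genes had 1 of 22 higher, 2 when adjusted over the list alone (median 0.078, adjusted p = 0.0248, adjusted p = 0.142 with an estimated correlation), namely the receptor gene Tnfrsf12a at 1.03. Oxidative stress genes under NRF2 had 4 of 18 higher, 6 and 2 lower when adjusted over the list alone (median 0.113, adjusted p = 0.027, adjusted p = 0.399 with an estimated correlation, slide-block median 0.101, adjusted p = 0.105). Among the 4 were Mt1 and Mt2, also counted as glucocorticoid targets. Inflammatory mediator genes had 2 of 16 higher, 3 when adjusted over the list alone (median 0.108, adjusted p = 0.027, adjusted p = 0.151 with an estimated correlation, slide-block median 0.09, adjusted p = 0.0592). Sele, an endothelial adhesion gene, rose by 0.92, while Cxcl1 (0.79), Ccl2 (0.35) and Il1b (0.06) did not pass.

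Markers of other cell types were measured in the same livers. Endothelial markers were higher at 5 g/kg in 4 of 14 cases, 6 when adjusted over the list alone (median 0.217, slide-block median 0.269, adjusted p = 0.00555, adjusted p = 0.142 with an estimated correlation), with the sinusoidal receptor gene Lyve1 at 1.29. Stellate cell and fibroblast markers rose in 2 of 13 cases, 3 when adjusted over the list alone (median 0.187, slide-block median 0.246, adjusted p = 0.00555, adjusted p = 0.142 with an estimated correlation), namely Hgf at 0.70 and Dcn at 0.74. Pericentral hepatocyte markers fell in 1 of 10 cases, also 1 when adjusted over the list alone (median −0.185, within slides −0.41 to 0.026, adjusted p = 0.0207, adjusted p = 0.189 with an estimated correlation). Kupffer cell markers (median −0.03), neutrophil markers (adjusted p = 0.231), lymphocyte markers (adjusted p = 0.145) and exocrine pancreas markers (adjusted p = 0.91) did not pass.

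**Figure D1:**
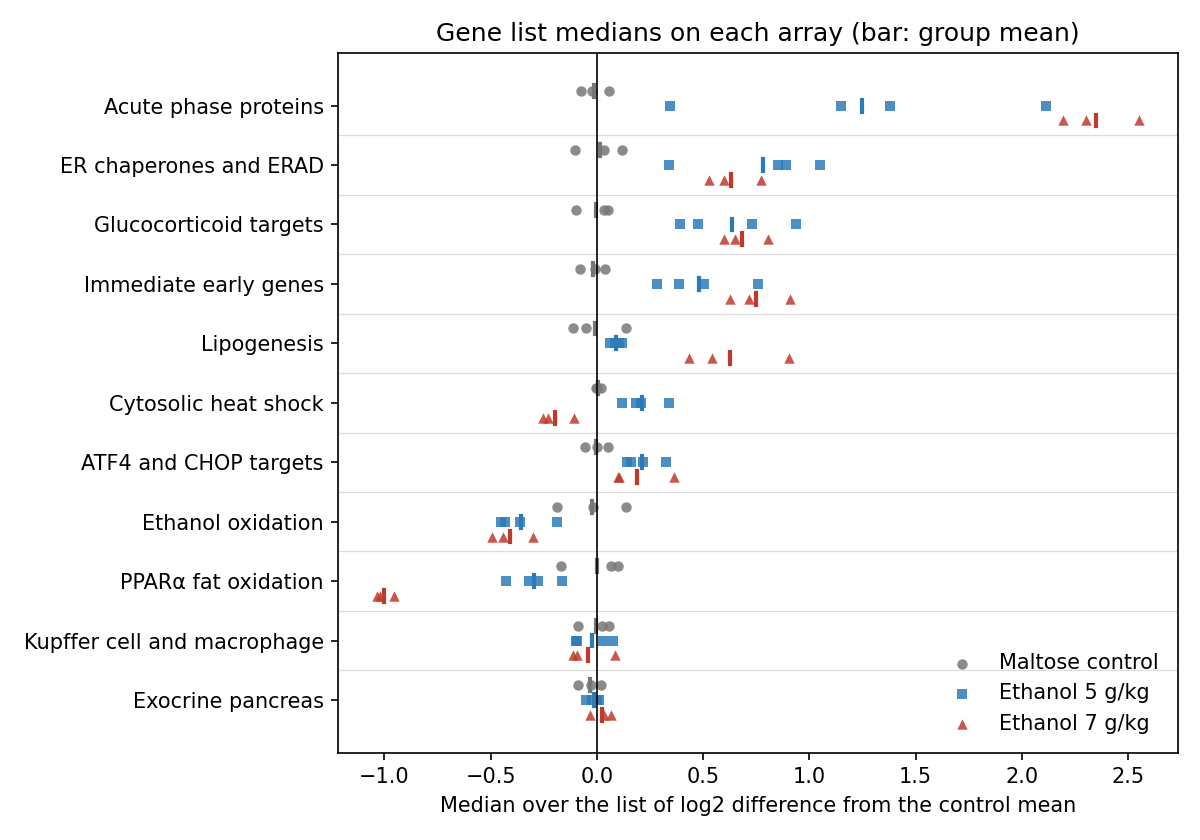
Median over each of 11 gene lists of the log2 difference from the control mean, 1 point per array (circles control, squares 5 g/kg, triangles 7 g/kg), with a bar at each group mean. The 5 g/kg arrays spread from 0.344 to 2.11 on the acute phase list, and the 7 g/kg arrays lie at −1.04 to −0.953 on the PPARα list. The list labelled as cytosolic heat shock also includes mitochondrial heat shock genes.

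The comparison of 7 g/kg ethanol with maltose asked the same at the higher dose, with a control matched in calories to 5 and not to 7 g/kg. Serum amyloid A genes rose most: Saa3 87.5-fold (log2 6.45, SE 0.834, adjusted p = 0.000207), Saa1 75.8-fold (log2 6.24, SE 0.843) and Saa2 67.3-fold (log2 6.07, SE 0.771), where Saa1 and Saa2 are so alike that their probes may share signal. Lcn2 rose 38.7-fold (log2 5.27, SE 0.496, adjusted p = 1.63e-05). The lipogenic genes Thrsp and Fasn rose 26.0-fold (log2 4.70, SE 0.456) and 10.4-fold (log2 3.38, SE 0.305). Cyp2c70 (4.11), Mt1 (4.07), Cyp2b13 (3.99) and Cyp2b10 (3.58) completed the 10 largest rises. Cyp4a14, a fatty acid ω-hydroxylase gene under PPARα, was 69.0-fold lower (log2 −6.11, SE 0.197, adjusted p = 4.58e-10), and the related gene Cyp4a31 was 30.2-fold lower (log2 −4.92, SE 0.247).

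Cyp7a1 was 8.47-fold lower at 7 g/kg (log2 −3.08, SE 0.387, adjusted p = 0.000169), with 2 of the 3 ethanol arrays well above background. Acot3 was at least 8.38-fold lower, since no 7 g/kg array stood well above background for it, and the related thioesterase gene Acot1 changed by −1.99. The other largest falls were in Apol7a (−2.44), Akr1c19 (−2.39, with a second probe at 0.089), Etnppl (−2.09), Tk1 (−2.07) and Dbp (−1.99). In all, 2355 genes passed, 1218 higher and 1137 lower, and 450 of them differed at least 2-fold. With slide as a block 1752 genes passed. Within slides, Saa1 rose by 5.90 to 6.38 and Fasn by 3.31 to 3.75, while Cyp4a14 changed by −5.98 to −5.66. The count was 1497 without control 1. Of the calls 51.7% were higher, and 67.0% were with median centring in place of the loess curve.

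PPARα target genes fell in 16 of 22 cases at 7 g/kg, 18 when adjusted over the list alone with 1 higher (median −0.929, slide-block median −0.898, within slides −1.04 to −0.851, adjusted p = 6.33e-22). This call held with an estimated correlation (adjusted p = 0.046). Cpt1a fell by 1.58. Lipogenic genes rose in 8 of 15 cases, 9 and 1 lower when adjusted over the list alone (median 0.671, slide-block median 0.672, within slides 0.484 to 0.825, adjusted p = 1.91e-07, adjusted p = 0.142 with an estimated correlation). Besides Fasn and Thrsp, Me1, which supplies NADPH, rose by 1.69 and the liver pyruvate kinase gene Pklr by 2.20, while Srebf1 stood at 0.70 (adjusted p = 0.282). Cholesterol synthesis genes went both ways, 7 of 21 higher and 3 lower, 7 and 4 when adjusted over the list alone, and the list did not pass (adjusted p = 0.31). Fdps rose by 1.79 and Dhcr7 by 1.37, and Fdft1 fell by 1.17. Lipid droplet and lipolysis genes did not pass either (4 of 19 higher, 2 lower, 5 and 3 when adjusted over the list alone, adjusted p = 0.31): Plin3 rose by 0.75 and the lipase activator gene Abhd5 by 0.67, while Pnpla2 (0.23), Lipe (−0.19), Plin2 (0.25) and Cidec (−0.14) did not pass.

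Acute phase genes rose in 18 of 20 cases at 7 g/kg, the same number when adjusted over the list alone (median 2.33, slide-block median 2.21, within slides 2.27 to 2.56, adjusted p = 2.39e-25, adjusted p = 0.142 with an estimated correlation). Besides the genes above, Orm1 rose by 2.87 and Serpina3n by 2.61. Inflammatory mediator genes rose in 4 of 16 cases, 5 when adjusted over the list alone (median 0.136, slide-block median 0.116, adjusted p = 0.0056, adjusted p = 0.142 with an estimated correlation). Cxcl1, a neutrophil-attracting chemokine gene, rose 6.36-fold (log2 2.67, SE 0.317, adjusted p = 0.000114) and the cytokine signalling inhibitor gene Socs3 rose by 0.93 (0.71 with slide as a block, adjusted p = 0.0568), while Ccl2 (0.30) and Il1b (0.05) did not pass. Neutrophil markers rose in 3 of 13 cases, also 3 when adjusted over the list alone (median 0.108, within slides 0.105 to 0.158, adjusted p = 0.0172, adjusted p = 0.275 with an estimated correlation). S100a9 rose by 1.40, Il1r2 by 0.74 (1 of 3 control arrays well above background), and S100a8 was at least 2.41-fold higher. Kupffer cell markers did not pass as a list (adjusted p = 0.539), with Adgre1 at −0.37 (adjusted p = 0.0655).

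ER chaperone genes rose in 8 of 17 cases at 7 g/kg, 12 when adjusted over the list alone (median 0.592, slide-block median 0.652, within slides 0.574 to 0.81, adjusted p = 2.92e-08, adjusted p = 0.197 with an estimated correlation). Creld2 rose by 1.19, Xbp1 by 1.02, Sec61b by 0.77 and Edem1 by 0.69. ATF4 and CHOP target genes rose in 4 of 20 cases and fell in 1, 5 and 1 when adjusted over the list alone (median 0.187, adjusted p = 0.00896, adjusted p = 0.197 with an estimated correlation, slide-block median 0.165, adjusted p = 0.0584). Ddit4 rose by 1.69 and Trib3 fell by 0.45 (−0.42 with slide as a block, adjusted p = 0.0703), while Ddit3 (0.06), Fgf21 (0.13) and Atf3 (0.71, adjusted p = 0.187) did not pass. Immediate early genes rose in 9 of 15 cases, 11 when adjusted over the list alone (median 0.723, slide-block median 0.633, within slides 0.455 to 0.932, adjusted p = 4.55e-08, adjusted p = 0.142 with an estimated correlation), led by the transcription factor genes Egr1 at 3.23 and Junb at 1.32. Glucocorticoid targets rose in 9 of 13 cases, also 9 when adjusted over the list alone (median 0.702, slide-block median 0.731, within slides 0.684 to 0.851, adjusted p = 8.43e-08), and this call held with an estimated correlation (adjusted p = 0.0463).

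Genes of ethanol oxidation fell in 6 of 11 cases at 7 g/kg and rose in 1, 6 and 2 when adjusted over the list alone (median −0.391, slide-block median −0.419, within slides −0.569 to −0.474, adjusted p = 0.00221, adjusted p = 0.151 with an estimated correlation). Cyp2e1 fell by 0.77, Adh4 by 1.40, Aldh3a2 by 1.27 and Adh1 by 0.39 (adjusted p = 0.0416, and −0.42 with slide as a block, adjusted p = 0.0769), while Acss2, which activates acetate, rose by 0.96 and Aldh2 stood at −0.01 (n = 2 and 2). The esterases and transferases able to use ethanol had 2 of 17 higher and 2 lower, 4 and 4 when adjusted over the list alone, and did not pass (median 0.004, mean −0.012, adjusted p = 0.893): Ces2e and Ces2c rose by 0.97 and 0.73, and Ces1f and Ces1d (n = 2 and 2) fell by 1.13 and 1.11. The glucose metabolism list rose, with 5 of 15 higher and 1 lower, 5 and 3 when adjusted over the list alone (median 0.29, slide-block median 0.521, adjusted p = 0.0286, adjusted p = 0.146 with an estimated correlation): Igfbp1 rose by 3.03. NRF2 target genes had 6 of 18 higher and 3 lower, 7 and 4 when adjusted over the list alone (median 0.225, within slides 0.031 to 0.166, adjusted p = 0.00506, adjusted p = 0.302 with an estimated correlation). Mt1, also counted as a glucocorticoid target, stood at 4.07, the glutathione transferase gene Gstm3 at 1.80 and heme oxygenase (Hmox1) at 1.01.

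The p53 target list (3 of 17 higher, 5 when adjusted over the list alone, median 0.147, adjusted p = 0.00485, adjusted p = 0.15 with an estimated correlation) and the cell death list (2 of 22 higher, 4 when adjusted over the list alone, median 0.14, adjusted p = 0.0225, adjusted p = 0.142 with an estimated correlation) also rose at 7 g/kg, with Cdkn1a at 2.56 and Tnfrsf12a at 1.32. Endothelial markers (3 of 14 higher, also 3 when adjusted over the list alone, median 0.21, slide-block median 0.29, adjusted p = 0.0176, adjusted p = 0.151 with an estimated correlation) and stellate cell markers (2 of 13 higher, 5 when adjusted over the list alone, median 0.209, slide-block median 0.321, adjusted p = 0.00896, adjusted p = 0.15 with an estimated correlation) rose too, with Lyve1 at 1.72 and Timp1 at 0.61. Xenobiotic P450 genes went both ways (6 of 18 higher, 5 lower, 6 and 6 when adjusted over the list alone), and the list did not pass (median −0.115, mean 0.235, test direction up, adjusted p = 0.98). Nr1i3, which encodes the nuclear receptor CAR, fell by 1.41.

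**Figure D2:**
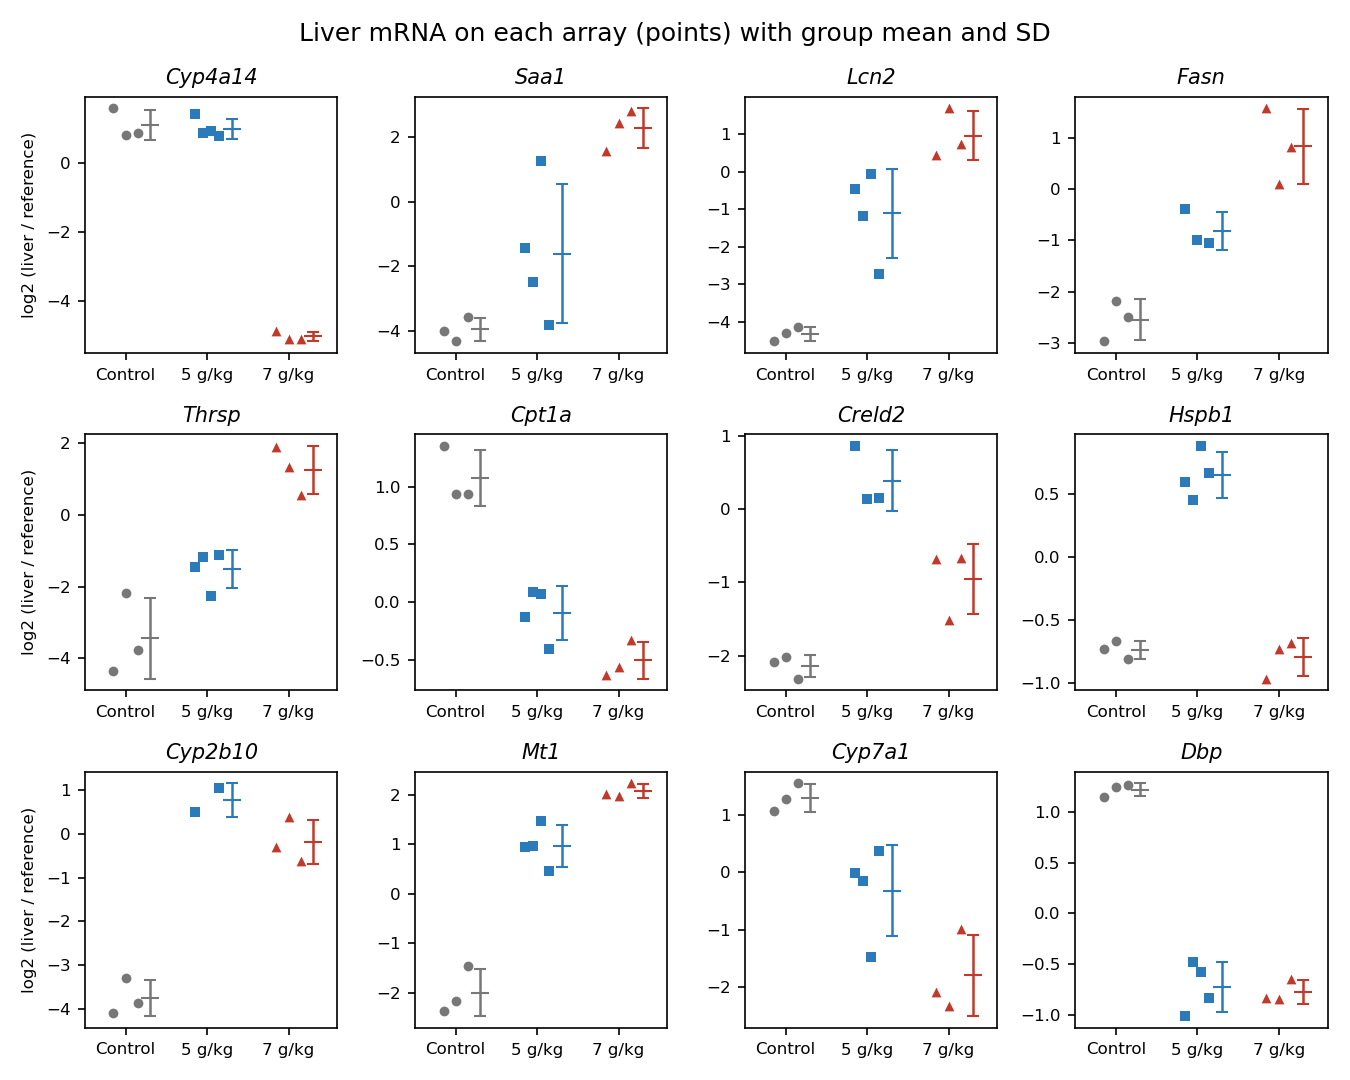
Log2 ratio of liver to reference signal for 12 genes, 1 point per array in the control, 5 g/kg and 7 g/kg groups, with the group mean and SD beside the points. Cyp4a14 was 64.4-fold lower at 7 than at 5 g/kg, and Hspb1 was 1.39 higher (log2) at 5 g/kg than in controls.

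The comparison of 7 with 5 g/kg tested the difference between the doses itself. Cyp4a14 was 64.4-fold lower at 7 than at 5 g/kg (log2 −6.01, SE 0.184, adjusted p = 2.25e-10), and Cyp4a31 was 22.7-fold lower (log2 −4.50, SE 0.231). Saa1 was 14.9-fold higher (log2 3.89, SE 0.788, adjusted p = 0.0215), as were Saa3 (3.82) and Saa2 (3.80) to a similar extent, and Lcn2 was higher by 2.06 (adjusted p = 0.0393). Carbonic anhydrase 3 (Car3) was 9.96-fold higher (log2 3.32, SE 0.488, adjusted p = 0.00288). Thrsp was higher by 2.76 (SE 0.427), and the sugar-metabolism genes Pgd (n = 2 and 4) and Pklr by 1.98 and 1.87. Egr1 and Cxcl1 were higher by 1.97 and 1.88. Lower at 7 than at 5 g/kg were Apoa4 (−1.67, n = 3 and 3), the chaperone genes Hsph1 (−1.53) and Hspb1 (−1.44, SE 0.116, adjusted p = 2.09e-05), Bhmt (−1.50), a methyl-donor enzyme gene, Vnn1 (−1.40), Creld2 (−1.34, n = 3 and 3), and the transporter genes Slco1a4 (−1.31) and Slc16a7 (−1.25, n = 3 and 3).

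Between the doses 410 genes passed, 173 higher and 237 lower at 7 g/kg, and 83 of them differed at least 2-fold. With slide as a block 341 genes passed. Within slides, Cyp4a14 changed by −6.03 to −5.71, Thrsp rose by 1.67 to 3.58 and Saa1 rose by 1.18 to 6.61. The count was 218 and 232 without the 7 g/kg arrays 1 and 2, and 268 and 231 without the 5 g/kg arrays 1 and 2. Of the calls 42.2% were higher, and 52.4% were with median centring in place of the loess curve.

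PPARα targets were lower at 7 than at 5 g/kg in 9 of 22 cases and higher in 1, 15 and 1 when adjusted over the list alone (median −0.508, slide-block median −0.496, within slides −0.663 to −0.345, adjusted p = 1.14e-20, adjusted p = 0.0523 with an estimated correlation). Hadhb, of mitochondrial β-oxidation, was lower by 1.03, while Cpt1a stood at −0.41 (adjusted p = 0.254). Lipogenic genes were higher in 6 of 15 cases, 9 when adjusted over the list alone (median 0.5, slide-block median 0.456, within slides 0.302 to 0.837, adjusted p = 2.43e-10, adjusted p = 0.132 with an estimated correlation). Fasn was higher by 1.65 (n = 3 and 3), Me1 by 1.51 and Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, by 0.79. Acute phase genes were higher in 9 of 20 cases, 14 when adjusted over the list alone (median 1.11, slide-block median 1.14, within slides 0.4 to 2.21, adjusted p = 4.62e-14, adjusted p = 0.328 with an estimated correlation), with Orm1 at 1.56. Xenobiotic P450 genes were lower in 3 of 18 cases and higher in 1, 9 and 1 when adjusted over the list alone (median −0.53, slide-block median −0.521, within slides −0.442 to −0.327, adjusted p = 1.63e-07, adjusted p = 0.0595 with an estimated correlation), with the heme synthesis gene Alas1 at −0.98 (−0.97 with slide as a block, adjusted p = 0.0539) and Nr1i3 at −0.81 (n = 3 and 3).

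Cytosolic and mitochondrial heat shock genes were lower at 7 than at 5 g/kg in 6 of 13 cases and higher in 1, the same when adjusted over the list alone (median −0.157, slide-block median −0.145, within slides −0.477 to −0.236, adjusted p = 1.21e-05, adjusted p = 0.157 with an estimated correlation). Besides Hspb1 and Hsph1, Hsp90aa1 (n = 3 and 3) was 2.15-fold lower and Hsp90ab1 was 1.71-fold lower. ER chaperone genes had 1 of 17 lower, Creld2, and 1 higher, Sec61b at 0.62 (0.64 with slide as a block, adjusted p = 0.0735), and 6 and 3 when adjusted over the list alone. Their list was lower (median −0.298, slide-block median −0.288, adjusted p = 0.00618), with adjusted p = 0.695 with an estimated correlation, and its median was 0.293 on slide 2 against −0.6 and −0.241 on slides 1 and 4. The call ended without the 5 g/kg array 1 (median −0.198, adjusted p = 0.0849) or the 7 g/kg array 2 (median −0.356, adjusted p = 0.0527). Without array 4 of the 5 g/kg group, which lay on slide 2, the median was −0.366 (adjusted p = 2.17e-07). NRF2 target genes were higher in 4 of 18 cases, 6 when adjusted over the list alone (median 0.143, within slides 0.099 to 0.142, adjusted p = 0.00618, adjusted p = 0.447 with an estimated correlation), among them Mt1 (1.11, also a glucocorticoid target), Gstm3 (1.07) and Hmox1 (0.65).

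Immediate early genes were higher in 3 of 15 cases, 4 when adjusted over the list alone (median 0.14, within slides 0.049 to 0.378, adjusted p = 0.00291, adjusted p = 0.447 with an estimated correlation). Junb, among the 3, turned to −0.088 with the series table and to −0.024 with outlier-marked spots kept. Growth hormone-dependent and sex-biased genes were higher in 1 of 12 cases, 3 when adjusted over the list alone (median 0.314, within slides −0.068 to 0.399, adjusted p = 0.00131, adjusted p = 0.278 with an estimated correlation), namely Selenbp2 at 1.06. Neutrophil markers were higher in 1 of 13 cases, 2 when adjusted over the list alone (median 0.07, within slides −0.029 to 0.211, adjusted p = 0.024, adjusted p = 0.447 with an estimated correlation), with S100a8 at 0.89. Periportal hepatocyte markers were lower as a list, with 3 of 8 lower when adjusted over the list alone and Aldh1b1, at −0.57 (adjusted p = 0.0688), nearest to passing over all genes (median −0.357, adjusted p = 0.0316, adjusted p = 0.627 with an estimated correlation, slide-block median −0.256, adjusted p = 0.144). Among genes of ethanol metabolism, Acss2 was higher by 1.30 and Aldh3a2 lower by 0.57 (−0.61 with slide as a block, adjusted p = 0.0512), and the list did not pass (adjusted p = 0.792).

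The changes at the 2 doses were set against each other across all 26124 genes, which are not independent replicates. Their log2 changes correlated at r = 0.779, where sharing the 3 controls alone gave 0.534 in 100 simulations of unchanged groups, 0.549 at most. The simulated genes varied independently and without slide effects, so 0.549 is not an upper limit for correlated genes. The covariance was 0.064 against 0.00959 simulated. Of the 992 genes called at 5 g/kg, 776 (78.2%) were called in the same direction at 7 g/kg. Higher at both doses were 455 genes and lower at both 321. Independent lists would share 27.1 and 17.8, but these values leave out the shared controls, from which part of the excess may come. The changes at 7 g/kg were larger for 56.7% of the genes called at 5 g/kg, and the median ratio of the change at 7 to that at 5 g/kg was 1.08. Since these genes were selected by their change at 5 g/kg, both values may understate the difference between the doses. Of the 2569 genes called at either dose, 14.1% passed the test between doses. Of the 410 genes that passed it, 330 were called at 7 g/kg against control in the direction of the difference between doses. This count does not ask for the direction of the change at 5 g/kg. Another 33 were called at 5 g/kg with a difference between doses in the opposite direction, so that effect was smaller, gone or reversed at 7 g/kg. The 2 genes called in opposite directions at the doses fall in both counts. Thrsp and Fasn were among the genes called in all 3 comparisons, 66 in number, and Cyp4a14 was among the 267 called at 7 g/kg and between doses but not at 5 g/kg.

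**Figure D3:**
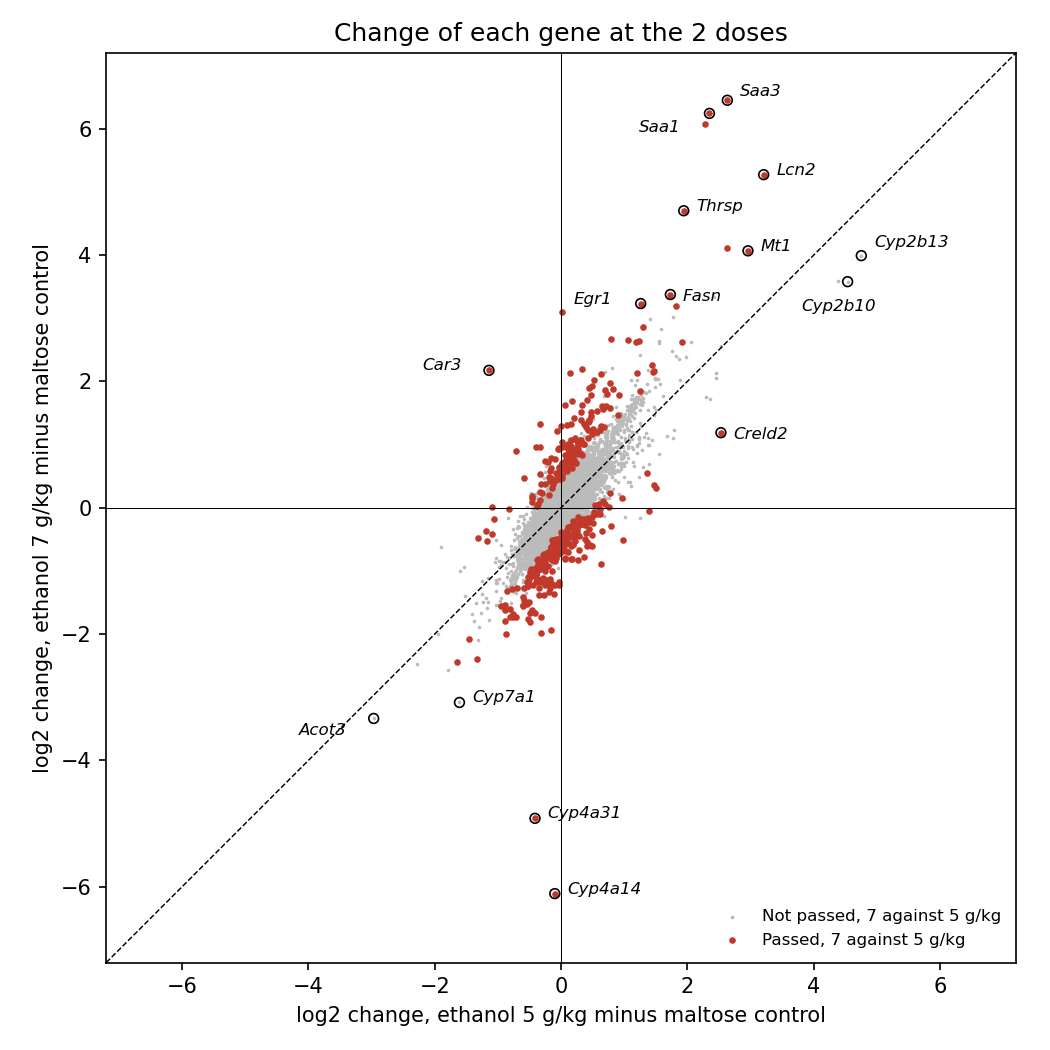
Log2 change at 5 g/kg (horizontal) against log2 change at 7 g/kg (vertical), both minus maltose control, 1 point per gene, with genes past the test between doses in red and the line of equality dashed. Cyp4a14 lies at −0.10 and −6.11, Creld2 at 2.53 and 1.19, and Saa1 at 2.35 and 6.24.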

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

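The tests weighed for PPARα targets, ER chaperones and Cyp2b genes, and the pair of genes with opposite calls, were chosen only after the results were seen, and the counts over other splits of the arrays were chosen before.

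Within the 5 g/kg group, 261 results were searched for an array far from the other arrays by Dixon's test. In the first search, over fewer results, 3 were found, and in this wider search 8 were found. Chance gives about 5% of those searched, so these 8 are no more than chance would give. The values are log2 ratios of liver to reference. Array 3 lay at −2.03 for Hsd3b5 (the others at −1.47 to −1.36) and at −0.041 for Gys2 (−0.441 to −0.377). Array 4 lay at −0.39 for Adh1 (−0.267 to −0.25). Array 2 lay at 0.03 for C1qa (−0.369 to −0.335) and at 0.289 for Gusb (0.008 to 0.019). Array 1 lay at −0.311 for Fdps (−0.613 to −0.563) and at 0.322 for Fitm2 (0.038 to 0.058). The median of the xenobiotic P450 list, as a log2 difference from the control mean, was −0.063 on array 2 and 0.11 to 0.129 on the others. Array 2 had no value for Cyp2b13, Cyp2b10 and Cyp2b9, which rose at 5 g/kg, and array 4 none for Cyp2b10 and Cyp2b9. The medians therefore cover different genes, and part of the gap may come from that.

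Only 2 genes were called in opposite directions at the doses, and both passed the test between doses. The probe NAP056541-1 changed by 0.403 at 5 g/kg and −0.603 at 7 g/kg, a difference of −1.01 (SE 0.098, adjusted p = 0.00012). Rtn4rl1 changed by 0.459 and −0.589, a difference of −1.05 (SE 0.118, adjusted p = 0.000387).

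PPARα target genes were lower at 7 than at 5 g/kg, by a median of −0.508. A difference between slides would let the shift vanish within slides, but the smallest of the 3 within-slide medians was still −0.345. This argues against slides as the whole cause, while the list had adjusted p = 0.0523 with an estimated correlation. A fed state at 7 g/kg cannot be told apart from an effect of the dose. It would lower genes of fasting and gluconeogenesis, whose median difference was 0.048 over 8 genes that went both ways, from −0.31 (Insig2, n = 2 and 4) to 1.26 (Igfbp1, n = 3 and 3, adjusted p = 0.133, and 1.61 with slide as a block, adjusted p = 0.0111). It would also raise lipogenic genes, which were higher by a median of 0.5, with Thrsp at 2.76 and Fasn at 1.65 (n = 3 and 3). Lower PPARα activity at the higher dose stays open and was not tested, and Ppara itself stood at 0.11.

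ER chaperone genes were lower at 7 than at 5 g/kg, by a median of −0.298 (adjusted p = 0.00618, and 0.695 with an estimated correlation). With 1 array left out the median ran from −0.485 to −0.198. The call ended without the 5 g/kg array 1 (−0.198, adjusted p = 0.0849) and without the 7 g/kg array 2 (−0.356, adjusted p = 0.0527), where the shift was smaller in the first case and larger in the second. An effect of 1 array therefore cannot be told apart from a difference between the doses. With slide as a block the median was −0.288 (adjusted p = 0.0287 by camera), but slide 2 gave 0.293 against −0.6 and −0.241 on slides 1 and 4. Since the sign turned on slide 2, a difference between slides stays open. The 5 g/kg array on that slide, array 4, had a list median of 0.34 from the control mean, against 0.852 to 1.05 on the others. On the same slide, control 3 had the lowest median of its group (−0.101) and the 7 g/kg array 3 the highest (0.773). Without the 5 g/kg array 4 the median between doses was −0.366 (adjusted p = 2.17e-07 by camera). This array cannot be told apart from its slide. A difference between the doses stays open too, and Creld2 was the single member lower by the test over all genes. Hspa5, whose marked spots were kept in an alternative chosen after seeing the data, stood at −1.09 between doses (adjusted p = 0.0639), with 5 of 10 spots affected.

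Cyp2b9, Cyp2b10 and Cyp2b13 rose together at 5 g/kg. They may be 1 transcript read by several probes, and this cannot be told apart from 3 separate rises: the further Cyp2b13 probe changed by 0.165 while the further Cyp2b9 probe changed by 3.20. A shift to female-type expression would raise other female-biased genes, but the median of 19 such genes without the Cyp2b genes was −0.097, with an upper quartile of 0.094, which argues against it. Ethanol exposure itself stays open and was not tested apart from the groups.

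Other splits of the arrays were fitted in the same way. For 5 g/kg against control, 1 of 35 splits, the real split, gave as many as 992 genes, the highest other being 224. This share is under 0.05 and is the smallest that 35 splits can give, so it argues against chance without excluding it. For lists it was also 1 of 35, with 18 against 17 in the highest other split. A split that called 0 genes also gave 17 lists. A margin of 1 list in 1 setting therefore does not exclude chance for the list count. The real count was 17 with the series table, 15 without the 5 g/kg array 3, 10 without control 3 and 1 with an estimated correlation, and the other splits were not fitted in those settings. Between doses, 1 of 35 splits gave 410 genes, the highest other being 66, which again argues against chance for the gene count without excluding it. For lists, 1 of 35 gave 11, the highest other being 10, and again a margin of 1 list in 1 setting does not exclude chance. The list count was 8 with the series table, 7 without the 7 g/kg array 2, 4 with fry and 0 by camera with an estimated correlation, where 5 lists had an unadjusted p under 0.05. For 7 g/kg against control the 10 splits are too few for a share under 0.05. The real split, 1 of 10, gave 2355 genes and 16 lists, and the highest others gave 1 gene and 15 lists.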

How the results depend on the processing

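The alternatives that kept outlier-marked spots or set slide as a block for lists and the agreement of doses were chosen after seeing the data. Where no cause is named, the cause was not tested. At 5 g/kg against control the count of 992 genes moved by more than 1.5 times with scanner processed signals (516), Cy5 alone (125), the series table (584), a threshold of 0.1 (1546) or at least 2-fold (204), and ran from 467 (without control 1) to 1049 over arrays left out, with 636 and 503 without controls 2 and 3. At 7 g/kg against control 2355 became 520 with Cy5 alone and 450 at 2-fold, and 1497 (without control 1) to 2346 over arrays left out. Between doses 410 became 114 with processed signals, 38 with Cy5 alone, 138 with the series table, 622 at a threshold of 0.1 and 83 at 2-fold, and 218 to 430 over arrays left out, the lowest without the 7 g/kg arrays 1 (218) and 2 (232) and the 5 g/kg arrays 2 (231) and 1 (268). Cy5 alone lacks the correction by the reference: its median SE was 0.195 to 0.209, against 0.12 to 0.128 for the ratio.

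Replicate numbers did not pair the arrays: residuals of arrays with the same number had a mean r of 0.027, −0.198 to 0.193. Slides paired them weakly. Between groups, arrays of the same slide had a mean r of 0.106 (−0.174 to 0.232), against −0.033 for other slides. For 8 of 10 arrays the best match in another group lay on the same slide, and the main fit does not account for this. With replicate number as a block 935, 2319 and 289 genes passed, and with slide as a block 909, 1752 and 341. List counts with an estimated correlation were 1, 2 and 0, fry gave 4 between doses, and leaving out arrays gave 10 (without control 3) to 21 lists at 5 g/kg and 7 (without the 7 g/kg array 2) to 14 between doses. The agreement of doses was r = 0.785 with median centring, 0.74 with the series table and 0.765 with slide as a block. Reversed were Ahsg at 5 g/kg (−0.08, Cy5 alone), Junb between doses (−0.088, series table, and −0.024, outlier-marked spots kept) and the hepatocyte list at 7 g/kg (−0.157, Cy5 alone). Of the called named genes, 34 of 86, 65 of 119 and 9 of 60 passed in the same direction in every setting, and of the called lists 1 of 18, 2 of 16 and 0 of 11. Signal over background limits some changes to lower bounds, such as those of Acot3 at 7 g/kg and Jun at 5 g/kg.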

Other observations

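The female-biased list and the values with outlier-marked spots kept were chosen only after the results were seen. Genes of the circadian clock and its output went both ways. At 5 g/kg 2 of 18 were higher and 4 lower, the same when adjusted over the list alone, and at 7 g/kg 3 were higher and 5 lower, 3 and 6 when adjusted over the list alone. The list did not pass camera at either dose (adjusted p = 0.0549 and 0.0528), although at 7 g/kg it did with slide as a block (median −0.143, adjusted p = 0.044). With fry it passed at both doses (adjusted p = 0.00463 and 0.00272). Members that go opposite ways can cancel in camera, so the camera result does not show that clock genes were unchanged. Per3, a clock gene, fell by 0.99 at 5 g/kg and 0.94 at 7 g/kg, and Tef, an output factor gene related to Dbp, fell by 0.76 and 1.05. Nfil3, a repressor of the targets of Dbp and Tef, rose by 0.83 and 1.28. Bile acid genes had 1 of 16 higher and 2 lower at 5 g/kg, 1 and 3 when adjusted over the list alone (adjusted p = 0.419), and 3 higher and 5 lower at 7 g/kg, 5 and 7 when adjusted over the list alone (adjusted p = 0.182). Besides Cyp7a1, the uptake transporter gene Slco1a4 fell by 1.80 and the phospholipid exporter gene Abcb4 by 1.07 at 7 g/kg, and Cyp7b1, of the alternative route of bile acid synthesis, rose by 0.96. Interferon-response genes had 1 of 20 higher and 3 lower at 7 g/kg, 2 and 3 when adjusted over the list alone (adjusted p = 0.396), with Tap1 at 1.44, Ifit1 at −0.75 and Ifit3 at −0.52.

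Among growth hormone-dependent and sex-biased genes, Igfals, which encodes a carrier of IGF1, fell by 1.02 at 5 g/kg and 1.19 at 7 g/kg, and the list did not pass against control (adjusted p = 0.145 and 0.45). A list of 19 female-biased genes had a median of −0.097 at 5 g/kg and −0.324 at 7 g/kg, where 7 members fell. Its camera test at the higher dose gave p = 3.08e-07, not adjusted over lists, and p = 0.00085 with an estimated correlation. Hepatocyte markers had 4 of 19 higher and 3 lower at 7 g/kg, 5 and 3 when adjusted over the list alone. The list did not pass (adjusted p = 0.897). Ahsg, a secreted glycoprotein gene, rose by a log2 of 1.23 at 5 g/kg and rose 2.14-fold at 7 g/kg. Its rise was not larger at 7 g/kg, with a log2 difference of −0.133 between doses that did not pass (adjusted p = 0.83). At 7 g/kg the tyrosine breakdown gene Hpd fell by a log2 of 1.18 and Cebpa, a hepatocyte transcription factor gene, by 0.80. The Ahsg rise at 5 g/kg was not seen in the Cy5 channel alone (−0.08). Oat, a pericentral gene, fell by 1.54 (n = 3 and 2), and the periportal gene Hal by 1.27, at 7 g/kg. Erythroid markers (adjusted p = 0.3 and 0.081), adipocyte markers (0.118 and 0.163), cell cycle genes (0.869 and 0.396) and reference genes (0.596 and 0.425) did not pass at 5 and 7 g/kg, although Actb, a common reference gene, rose by 0.73 and 0.78. Cholangiocyte markers did not pass either (0.936 and 0.87), and their median at 5 g/kg (0.087) and mean (−0.033) differed in sign.

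The genes Hspa5, Scd1 and Atf4 were left out because of outlier-marked spots, and were also measured with those spots kept. Hspa5, the main ER chaperone gene, was 4.07-fold higher at 5 g/kg (log2 2.03, adjusted p = 0.000783) and stood at 0.94 at 7 g/kg (adjusted p = 0.0586), with 5 of 10 spots affected. Scd1, a fatty acid desaturase gene, stood at 0.60 at 5 g/kg (adjusted p = 0.314) and rose by 2.65 at 7 g/kg (adjusted p = 7.24e-05), with 8 of 10 spots affected. Atf4 stood at 0.194 and 0.155.

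The reference channel alone was tested between groups by limma as a control. It called 0, 1 and 0 genes in the 3 comparisons, the 1 gene being also called by the ratio, with 117, 257 and 225 genes at an unadjusted p under 0.05. Over the genes called by the ratio, the median size of the reference change was 0.066, 0.093 and 0.083, where the median SE of a reference change over all genes was 0.181, 0.194 and 0.182. Signals of the liver and reference channels correlated at r = 0.984 to 0.989 across probes within an array, where probes are not independent replicates. In the control livers, acute phase genes had a median log2 ratio to the reference of −1.36, ER chaperone genes of −0.669, lipogenic genes of −0.393 and PPARα targets of 0.542. Hepatocyte markers stood at a median of 0.207 (−0.34 to 1.07) and exocrine pancreas markers at −0.112 (−0.519 to 0.228). A mix of many tissues would leave hepatocyte markers in liver far above the reference. These values argue against liver being a small part of it.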
